A study of Mus musculus with 20 samples.

How the data were processed

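RNA sequencing of 20 mouse tenocyte libraries was used, 4 at each of 0, 1, 2, 6 and 24 h of 100 ng/mL IGF1. Groups and replicate numbers were taken from the labels. The authors deposited a table of raw read counts per gene for 29986 genes, which holds whole numbers with column sums that differ between libraries. The submitters' processing notes name FastQC, STAR, edgeR and the mm10 build, without versions. The counting tool, the annotation release and the use of strand in counting are not given in the sources used here. The authors also deposited a table of edgeR results with log2 fold changes, average log2 CPM, raw p-values and adjusted p-values (FDR) per comparison, per the file headers. The model, test and filter behind that table are not given in the sources used here, and it was used only for the comparison at the end of the report.

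Counts were analysed as deposited with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr over the 5 groups, which kept 14420 genes with 99.9% of the counts. Libraries were scaled by TMM, dispersions were estimated robustly, and all 20 libraries entered 1 quasi-likelihood fit without covariates, so that the groups share 1 estimate of the spread. Contrasts were each of 4 treated times against 0 h and 3 steps between successive times, and a test with 4 coefficients gave the genes that changed at any time. The SE of a log2 fold change is its size divided by the square root of the F statistic. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Sequencing depth ranged from 13734425 to 22687173 counts per library, and the mean total at 24 h was 0.734 of that at 0 h. Mitochondrial genes held 1.31% to 1.75% of the counts. The labels name no batch. The first 3 principal components held 23.6%, 17.9% and 9.39% of the variance.

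The labels of 0 h replicate 2 carry the description of 0 h replicate 1. A chi-square test of the counts of these libraries gave 9.28 per degree of freedom, within the 2.99 to 57.4 of the replicate pairs, so they differ by more than sampling noise and each was counted as 1 replicate. The test cannot tell whether both libraries came from the same culture.

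The rule for the genes named in the text, the gene lists, the tests and most alternatives were chosen before the data were examined. For each comparison with 0 h the rule took up to 8 rising and 8 falling genes of the largest fold change among called genes with a mean CPM of at least 5 in the higher group and no overlap of the 4 and 4 libraries, leaving out gene models without a name. It also took up to 4 called members of each list and time, 3 genes per direction for each step, and always Igf1, Igf1r, Insr, Irs2, Scx, Mkx, Tnmd, Col1a1, Col1a2 and Col3a1. The text leaves out some of the genes that the rule allows. Genes named in a count of few members are also given.

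A total of 35 gene lists with 566 entries was used, of which 564 were in the count table and 538 were tested. They cover signalling and transcription (immediate early genes, ERK feedback regulators, FoxO targets, the IGF axis, p53 targets, the TGF-beta pathway, the circadian clock, interferon response and inflammatory genes), biosynthesis and metabolism (ribosome biogenesis, ribosomal proteins, translation factors, Atf4 targets, cholesterol, fatty acid synthesis, glycolysis and hypoxia), the cell cycle (G1 and S phase, G2 phase and mitosis, kinase inhibitors), matrix and cytoskeleton (tendon markers, collagens, collagen processing, glycoproteins, proteases, actin and SRF or YAP targets), proteostasis (autophagy, ER chaperones), and 8 lists of markers of other cell types. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over 140 tests of 35 lists at 4 times. The same test was run with a correlation estimated per list. Of 48 list calls, 20 held with the estimated correlation: 5 at 1 h, 4 at 2 h, 5 at 6 h and 6 at 24 h. Members were counted at the adjusted p over all genes and at one adjusted over the list alone.

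Gene positions come from GENCODE release M21, which uses the same build, and all 136 named genes had one. Of these 136, 10 share exonic bases with a tested gene on the opposite strand, and because the use of strand is unknown their reads cannot be told apart from the partner's. The shared part is 57.2% of the exonic bases of Fosl1 (with Ccdc85b), 18.0% of Dbp, 17.4% of Ccne2, 12.1% of Hmgcs1, 8.55% of Nr1d1, 6.42% of Plod2, and at most 1.09% of Dkc1, Dusp1, Map1lc3b and Nop56. Some genes that the naming rule allows are not reported here.

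The alternatives were RLE scaling, no count filter, a filter of CPM of at least 1 in at least 4 libraries, DESeq2 1.42.0, the replicate number as a block, 1 surrogate variable from sva 3.50.0, fits of only the 8 libraries compared, and leaving out each library in turn. For the lists they were the estimated correlation, fry, the block, RLE and a prior count of 0.5. Leaving out 2 h replicates 1 and 2, leaving out 2 h replicates 2 and 4, adding the mean log2 CPM of the macrophage markers as a term, and leaving out each library in the list tests were chosen after seeing the data.

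The fit was tested on simulated counts for 14420 genes, with changes made at 1 h only. The mean CPM and dispersion of each gene and the library sizes came from all 20 libraries. Genes were drawn independently, with the same dispersion at every time. The simulation therefore does not test a wider spread of the 2 h libraries or correlation between genes. Of 50 genes changed at each size, 68% were recovered at 1.5-fold, 78% at 2-fold, 90% at 3-fold and 96% at 4-fold. Unchanged genes made up 5.41% of the calls, and 1 gene was called at 2 h, where none had been changed. In the same simulation, camera of limma gave an unadjusted p-value of 2.3e-25 for a shifted list, and values of 0.616 and 0.435 for unchanged lists. Figures were drawn with matplotlib 3.10.9.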

Results

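Tenocytes, the fibroblast-like cells of tendon, were isolated from the tail tendons of adult C57Bl/6 mice and treated with 100 ng/mL of recombinant insulin-like growth factor 1 (IGF1) for 0, 1, 2, 6 or 24 h. Messenger RNA was measured by RNA sequencing in 20 libraries, 4 per time. The comparisons answer which transcripts change with the length of the IGF1 treatment. Total counts per library ranged from 13734425 to 22687173. Their means were 20764603 ± 1638115 at 0 h, 18546539 ± 2922172 at 1 h, 18823550 ± 1616867 at 2 h, 18693201 ± 1429119 at 6 h and 15239349 ± 1304669 at 24 h (SD, n = 4). Of 29986 genes, 14420 were tested, holding 99.9% of the counts. Fold changes are log2 ± SE against 0 h unless another time is named. Levels are CPM (counts scaled by library size) ± SD, with n = 4 per time throughout. P-values are Benjamini-Hochberg adjusted values of edgeR's quasi-likelihood test unless a list test is named. The labels do not say whether the 4 replicates of a time came from separate mice or cultures. The spread between libraries that the p-values and SEs rest on may therefore be technical. That spread is 1 estimate shared by all 20 libraries, likely too small for 2 h and too large for the other times. Untreated cultures kept for 1, 2, 6 or 24 h were not analysed here, so each comparison holds both the IGF1 treatment and the time in culture. Across the 5 times, 9188 genes (63.7% of those tested) changed.

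**Figure D1:**
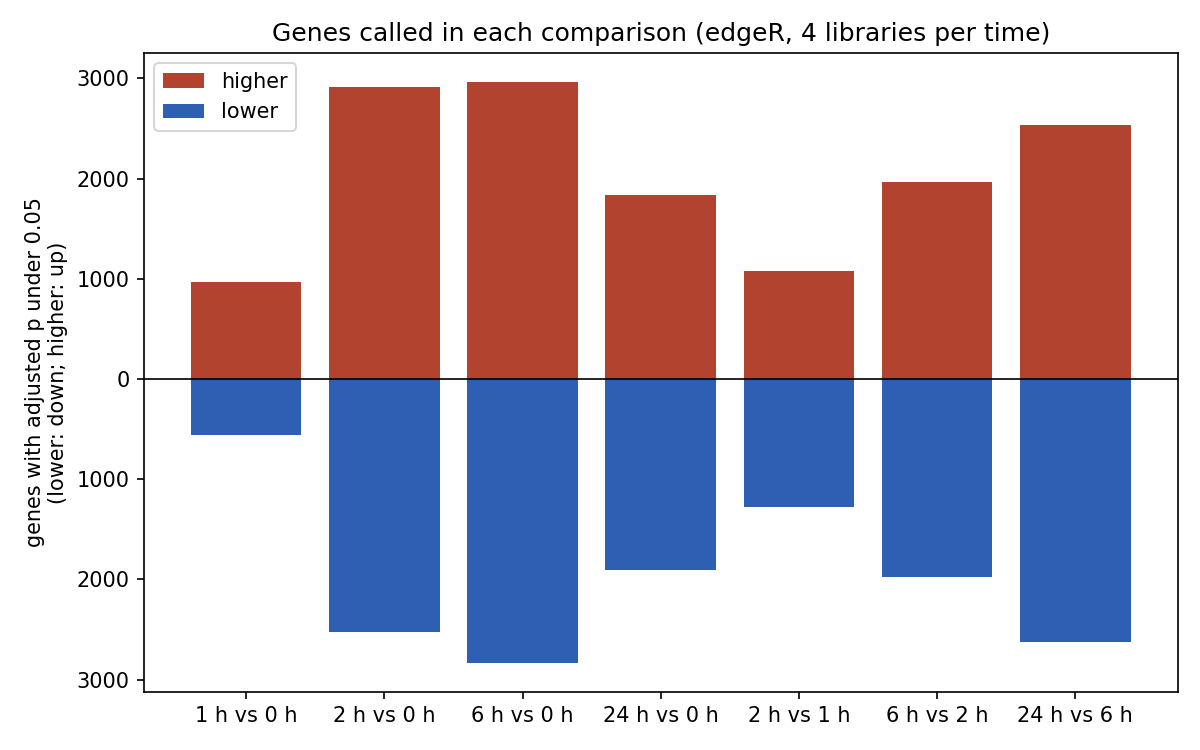
Number of genes with an adjusted p under 0.05 in each of the 7 comparisons (horizontal axis), with genes higher at the later time drawn upward and genes lower drawn downward (vertical axis, number of genes). The counts against 0 h were 1533 at 1 h, 5443 at 2 h, 5797 at 6 h and 3746 at 24 h.

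After 1 h of IGF1, transcripts of growth factor-induced transcription factors rose and transcripts of genes repressed by insulin and IGF signalling fell. Klf10, a zinc finger repressor, rose from 15.1 ± 2.61 to 104 ± 3.93 CPM (log2 2.77 ± 0.10, adjusted p = 1.07e-16). The Notch target repressor Hes1 rose by 2.71 ± 0.13, the repressor Snai1 by 2.41 ± 0.12, Arc by 2.39 ± 0.22 and Egr3 by 2.36 ± 0.21. The Notch-modifying glycosyltransferase Lfng rose by 2.13 ± 0.20, the AP-1 component Fosl1 by 2.08 ± 0.11 and the EGF receptor ligand Hbegf by 1.99 ± 0.087. Irs2, the adaptor that links the insulin and IGF1 receptors to PI3 kinase, changed by −2.32 ± 0.15, from 37.9 ± 2.45 to 7.64 ± 1.16 CPM (adjusted p = 5.47e-12). The transcription factor Klf15 (−1.99 ± 0.13), the atypical cyclin Ccng2 (−1.95 ± 0.15), the pro-apoptotic Bbc3 (−1.92 ± 0.12), the coactivator Pnrc1 (−1.87 ± 0.077) and the kinase Pim1 (−1.63 ± 0.12) also fell. In each of these genes, as the rule for naming them requires, the 4 libraries at 1 h lay outside the range of the 4 at 0 h. In all, 1533 genes were called, 973 higher and 560 lower, with 93 at least 2-fold higher and 86 at least 2-fold lower. The count was 2429 with 2 h replicates 2 and 4 left out, an alternative chosen after seeing the data.

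In the reference annotation of the mm10 build, Klf10 (ENSMUSG00000037465) lies on chromosome 15, bases 38291463 to 38300706, minus strand. Irs2 (ENSMUSG00000038894) lies on chromosome 8, bases 10984681 to 11008458, minus strand. Scx (ENSMUSG00000034161) lies on chromosome 15, bases 76457452 to 76459458, plus strand. Igf1r (ENSMUSG00000005533) lies on chromosome 7, bases 67952827 to 68233668, plus strand, and Igfbp5 (ENSMUSG00000026185) on chromosome 1, bases 72857932 to 72874884, minus strand. All 5 are protein-coding, and their values are counts over the whole gene.

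Of the 35 lists, camera called 10 at 1 h, and 5 of these also with an estimated correlation. Of the immediate early genes, which are transcribed within minutes of a growth stimulus, 14 of the 22 tested members rose and 1 fell (15 and 3 adjusted over the list alone) (camera adjusted p = 6.23e-12, adjusted p = 0.0317 with an estimated correlation). Nr4a3 (1.82 ± 0.21) was among them, beside Klf10, Egr3 and Fosl1. Of the feedback regulators of ERK signalling, 5 of the 11 tested members rose and 1 fell (6 and 3 adjusted over the list alone). Spry4 was at 1.79 ± 0.12, Phlda1 at 1.46 ± 0.14 and Dusp5, a nuclear ERK phosphatase, at 1.38 ± 0.19, and the list had a camera adjusted p of 0.00234 and an adjusted p = 0.168 with an estimated correlation. Of the FoxO target genes, which FoxO transcription factors switch on when insulin or IGF signalling is low, 11 of the 19 tested members fell and 1 rose (17 and 1 adjusted over the list alone). Irs2, Klf15 and Ccng2 were in front, Txnip was at −1.48 ± 0.076, and the list had a camera adjusted p of 4.30e-16 and an adjusted p = 0.00138 with an estimated correlation. Of the genes of cholesterol synthesis and uptake, 18 of the 24 tested members rose and 0 fell (21 and 0 adjusted over the list alone). Hmgcs1 was at 0.94 ± 0.067 and Idi1 at 0.87 ± 0.10, and the list had a camera adjusted p of 2.35e-26 and an adjusted p = 0.00201 with an estimated correlation. Of the ribosome biogenesis genes, 12 of the 31 tested members rose and 0 fell (18 and 0 adjusted over the list alone). The snoRNP protein Nop56 was at 0.64 ± 0.059 and the RNA polymerase I subunit Polr1b at 0.51 ± 0.084, and the list had a camera adjusted p of 7.47e-11 and an adjusted p = 0.0120 with an estimated correlation. Of the inflammatory cytokines and NF-kB targets, 8 of the 17 tested members rose and 0 fell (11 and 0 adjusted over the list alone). The chemokines Ccl7 (1.55 ± 0.079), Ccl2 (1.45 ± 0.099) and Cxcl1 (1.41 ± 0.18) and the cytokine Lif (1.38 ± 0.12) were among them, and the list had a camera adjusted p of 9.50e-12 and an adjusted p = 0.00395 with an estimated correlation.

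Further lists called at 1 h were those of metabolism and autophagy. Of the glycolysis and hypoxia response genes, 7 of the 21 tested members rose and 0 fell (9 and 1 adjusted over the list alone). The glycolytic activator Pfkfb3 was at 0.79 ± 0.13 and hexokinase 2 (Hk2) at 0.67 ± 0.11, and the list had a camera adjusted p of 7.27e-05 and an adjusted p = 0.353 with an estimated correlation. Of the genes of amino acid transport, synthesis and tRNA charging, targets of Atf4, 5 of the 26 tested members fell and 0 rose (8 and 0 adjusted over the list alone). Chac1 was at −0.85 ± 0.13 and Trib3 at −0.84 ± 0.097, and the list had a camera adjusted p of 3.79e-06 and an adjusted p = 0.423 with an estimated correlation. Of the autophagy and lysosome genes, 5 of the 16 tested members fell and 0 rose (6 and 0 adjusted over the list alone). Atg14 was at −0.84 ± 0.13, and the list had a camera adjusted p of 0.00365 and an adjusted p = 0.249 with an estimated correlation. Of the fatty acid synthesis genes, 5 of the 11 tested members rose and 0 fell (5 and 1 adjusted over the list alone). Fatty acid synthase (Fasn) was at 0.79 ± 0.12, and the list had a camera adjusted p of 0.0431 and an adjusted p = 0.541 with an estimated correlation. The call for this last list was lost with RLE normalization (adjusted p = 0.0540) and without any 1 of 0 h replicate 1 (0.0600), 0 h replicate 3 (0.0774), 1 h replicate 2 (0.137), 1 h replicate 3 (0.0804), 6 h replicate 4 (0.0521), 24 h replicate 1 (0.0582), 24 h replicate 3 (0.0531) or 24 h replicate 4 (0.0538).

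**Figure D2:**
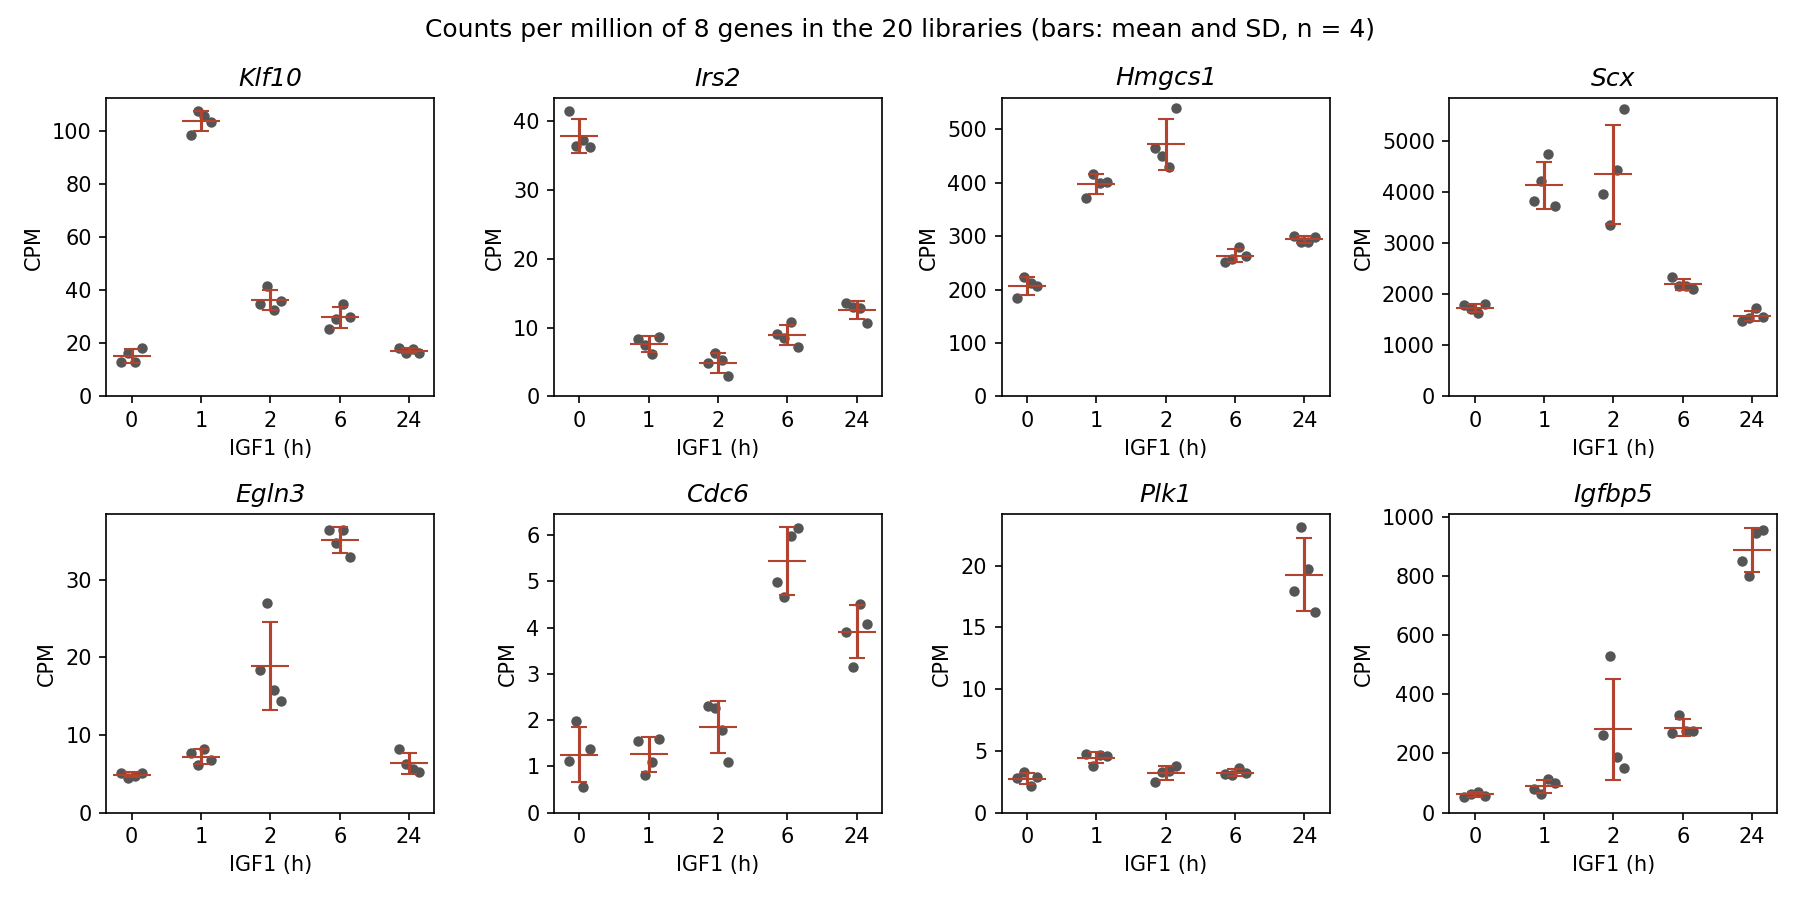
CPM (vertical axis, linear, from 0) of 8 genes at each IGF1 time in hours (horizontal axis), with 1 grey point per library and red bars for the mean and SD of 4 libraries. Klf10 peaked at 1 h with a mean of 104 CPM, Egln3 at 6 h with 35.1, and Plk1 and Igfbp5 were highest at 24 h with 19.2 and 888.

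After 2 h of IGF1, the list of FoxO target genes was lower than at 0 h, and the ribosome biogenesis, cholesterol and inflammatory lists were higher. Irs2 was at −2.96 ± 0.15, Klf15 at −2.91 ± 0.14 and Pim1 at −2.90 ± 0.13. The transcriptional corepressor Runx1t1 fell from 29.7 ± 1.94 to 4.44 ± 0.402 CPM (−2.73 ± 0.11, adjusted p = 4.98e-16), and the repressor Klf11 was at −2.53 ± 0.13, Klhl24 at −2.50 ± 0.15 and Arid5b at −2.44 ± 0.10. Fosl1 was at 78.2 ± 12.1 CPM (2.73 ± 0.11), and the semaphorin Sema7a rose by 2.52 ± 0.28, with 2 h replicate 2 at 30.2 CPM and the other 3 libraries between 11.5 and 12.8. In total 5443 genes were called, 2916 higher and 2527 lower, with 525 at least 2-fold higher and 280 at least 2-fold lower. The count was 3654 in a fit of only the 8 libraries compared. It was 3238 when the macrophage marker level of each library was a term in the fit, an alternative chosen after seeing the data. The marker level was higher in every 2 h library than in any 0 h library. Such a term therefore also takes up part of any difference between these times, whatever its cause.

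Several of the genes with the largest rise at 2 h are known from macrophages or Schwann cells, and their 4 libraries at 2 h were far apart. The neurotrophin receptor Ngfr was at 13.3 ± 20.4 CPM at 2 h and 0.924 ± 0.287 at 0 h (3.86 ± 1.08, adjusted p = 0.0103), with 2 h replicate 2 at 43.92 CPM and the other 2 h libraries between 1.957 and 5.31. Its call was lost without 2 h replicate 2 (1.78, adjusted p = 0.109), without 2 h replicates 1 and 2 (1.16, 0.378) or 2 and 4 (1.985, 0.120), with the macrophage marker level as a term (−0.57, 0.316) and in a fit of only the 8 libraries compared (3.87, 0.0722). The macrophage metalloelastase Mmp12 was at 216 ± 280.3 CPM at 2 h and 18.6 ± 3.50 at 0 h (3.54 ± 0.83, adjusted p = 0.00327), the integrin Itgax at 28.4 ± 28.4 and 3.82 ± 0.809 (2.90 ± 0.66), and Atp6v0d2 at 41.4 ± 39.3 and 7.38 ± 1.00 (2.49 ± 0.60). All 13 macrophage markers rose at 2 h, 13 also adjusted over the list alone, by log2 0.83 to 2.21, with the leukocyte phosphatase Ptprc at 2.21 ± 0.52 and Cd68 at 1.49 ± 0.39 (camera adjusted p = 1.86e-04, adjusted p = 0.556 with an estimated correlation). The mean log2 CPM of these markers was 4.40, 5.25, 3.78 and 3.89 in 2 h replicates 1 to 4, between 3.12 and 3.30 at 0 h, and between 2.49 and 4.20 in the other libraries. The Schwann cell, endothelial, and pericyte and smooth muscle markers were also highest in 2 h replicate 2 of all 20 libraries (mean log2 CPM 2.84, 2.32 and 2.78, others at most 1.56, 1.48 and 1.74). Without 2 h replicate 2, Mmp12 was at 2.13, Atp6v0d2 at 1.66, Ptprc at 1.46 and Cd68 at 0.93, all still called. Without 2 h replicates 1 and 2, 0 of the 13 markers was called higher by edgeR (1 at an unadjusted p under 0.05) and 1 by DESeq2 (2 unadjusted). With only 2 h replicates 3 and 4 left, the 13 markers still lay at log2 0.32 (Adgre1) to 0.95 (C1qb, adjusted p = 0.0583) by edgeR. In that edgeR fit Mmp12 was at 0.53 (adjusted p = 0.417), Itgax at 0.88 (0.176) and Atp6v0d2 at 0.79 (0.205). With the marker level as a term, these 3 genes fell to 0.15, 0.35 and 0.15 and were not called (adjusted p = 0.885, 0.547 and 0.718). Because that term also takes up part of any difference between 2 h and 0 h, these losses cannot tell a share of cells from a response. In a fit of only the 8 libraries compared these 3 genes were at 3.55, 2.90 and 2.50, about as with all libraries, but missed the threshold (0.0726, 0.0507 and 0.0526).

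Lists of ribosome biogenesis, cholesterol, glycolysis, fatty acid synthesis and signaling genes rose at 2 h. Of the ribosome biogenesis genes, 27 of the 31 tested members rose and 0 fell (29 and 0 adjusted over the list alone). Nop56 was at 1.06 ± 0.059 and Nip7 at 0.95 ± 0.086, and the list had a camera adjusted p of 2.82e-16 and an adjusted p = 0.00268 with an estimated correlation. Of the cholesterol genes, 23 of the 24 tested members rose and 0 fell (24 and 0 adjusted over the list alone). Hmgcs1 was at 1.19 ± 0.068, and the list had a camera adjusted p of 4.21e-23 and an adjusted p = 0.00268 with an estimated correlation. Of the glycolysis and hypoxia response genes, 17 of the 21 tested members rose and 0 fell (17 and 1 adjusted over the list alone). The prolyl hydroxylase Egln3 was at 1.96 ± 0.16 and Pfkfb3 at 1.79 ± 0.13, and the list had a camera adjusted p of 1.12e-10 and an adjusted p = 0.0874 with an estimated correlation. Of the fatty acid synthesis genes, 7 of the 11 tested members rose and 0 fell (7 and 0 adjusted over the list alone). Fasn was at 1.07 ± 0.12, and the list had a camera adjusted p of 0.00209 and an adjusted p = 0.323 with an estimated correlation. Of the inflammatory cytokines and NF-kB targets, 14 of the 17 tested members rose and 0 fell (14 and 0 adjusted over the list alone). Ccl2 was at 2.11 ± 0.10, Cxcl1 at 1.95 ± 0.18 and Ccl7 at 1.86 ± 0.079, and the list had a camera adjusted p of 9.85e-10 and an adjusted p = 0.00772 with an estimated correlation. The macrophage marker level of 2 h replicates 1 and 2 stood above the rest beside this list, whose call held without them. Of the immediate early genes, 14 of the 22 tested members rose and 4 fell (14 and 4 adjusted over the list alone). Egr2 was at 1.67 ± 0.22 and the MAP kinase phosphatase Dusp1 at −1.31 ± 0.11, and the list had a camera adjusted p of 0.00201 and an adjusted p = 0.402 with an estimated correlation. Of the ERK feedback regulators, 6 of the 11 tested members rose and 1 fell (7 and 1 adjusted over the list alone). Phlda1 was at 1.78 ± 0.13, and the list had a camera adjusted p of 8.96e-04 and an adjusted p = 0.127 with an estimated correlation.

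Lists with a fall at 2 h were led by the FoxO targets. Of these, 14 of the 19 tested members fell and 1 rose (15 and 1 adjusted over the list alone), and the riser was Ddit4, an inhibitor of mTORC1 (1.84 ± 0.089) (camera adjusted p = 5.95e-09, adjusted p = 0.00770 with an estimated correlation). Of the Atf4 targets, 12 of the 26 tested members fell and 0 rose (12 and 0 adjusted over the list alone). Trib3 was at −1.02 ± 0.098 and the cystine transporter Slc7a11 at −0.95 ± 0.084, and the list had a camera adjusted p of 1.68e-05 and an adjusted p = 0.480 with an estimated correlation. Of the autophagy and lysosome genes, 8 of the 16 tested members fell and 2 rose (9 and 2 adjusted over the list alone). The lysosomal regulator Tfeb was at 1.19 ± 0.15 and Atg14 at −1.04 ± 0.13, and the list had a camera adjusted p of 0.0400 and an adjusted p = 0.423 with an estimated correlation. That call was lost without 2 h replicate 1 (adjusted p = 0.0876), without 2 h replicate 3 (0.119) and without 2 h replicates 1 and 2 (0.0723). Of the actin cytoskeleton and SRF or YAP targets, 5 of the 14 tested members fell and 1 rose (5 and 1 adjusted over the list alone). Connective tissue growth factor (Ctgf) was at −1.43 ± 0.20, and the list had a camera adjusted p of 0.0392 and an adjusted p = 0.353 with an estimated correlation. Its call was lost without 2 h replicate 1 (0.0578), without 2 h replicate 2 (0.0579), without both (0.138) and with the macrophage marker level as a term (0.160). The ribosomal protein and p53 target lists missed the threshold of camera at 2 h (0.133 and 0.134). The ribosomal protein list passed it without 2 h replicate 1 (0.0302), without 2 h replicate 2 (0.0102), without both (3.98e-05) and with the macrophage marker level as a term (0.0205). Its mean log2 CPM was 9.001 in 2 h replicate 4 and between 8.425 and 8.538 in the other 2 h libraries, and without 2 h replicate 4 its adjusted p was 0.722. The p53 target list passed the threshold without 2 h replicate 4 (0.0488), and fry, which tests a list without other genes, called it lower with all libraries (1.28e-04). In 2 h replicate 4 longer transcripts were lower than in the other 2 h libraries (Spearman correlation across genes −0.74, where genes are not independent replicates).

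**Figure D3:**
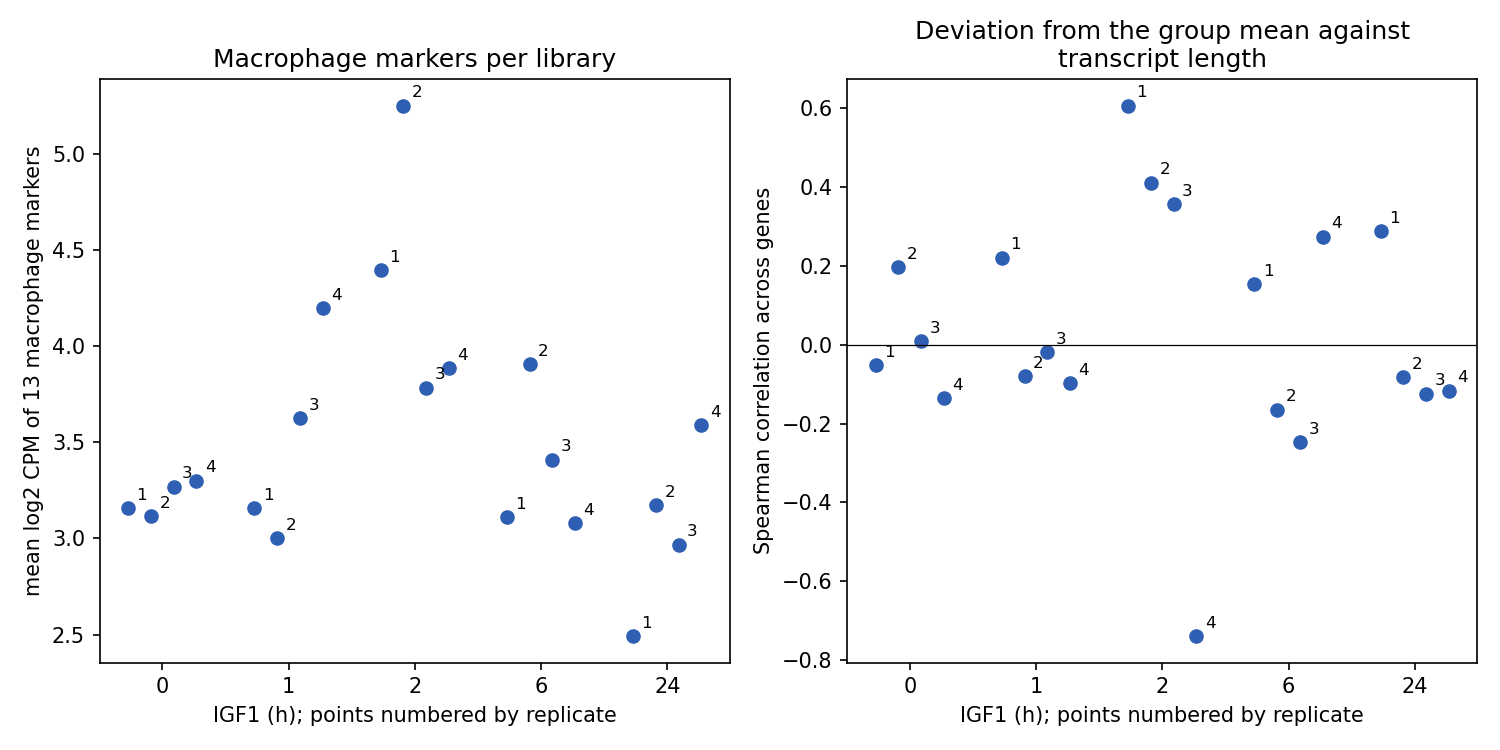
Left, the mean log2 CPM of the 13 macrophage markers in each library (vertical axis) at each IGF1 time in hours (horizontal axis), and right, the Spearman correlation across 9436 genes between a library's deviation from its time's mean and transcript length, with points numbered by replicate. On the left 2 h replicate 2 is highest at 5.25, and on the right 2 h replicate 4 is lowest at −0.74.

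After 6 h of IGF1, genes of the hypoxia response, ribosome biogenesis and the entry into S phase were higher than at 0 h. Apelin (Apln), a secreted peptide, rose from 6.12 ± 1.47 to 49.8 ± 6.35 CPM (3.03 ± 0.20, adjusted p = 5.45e-10). Egln3 rose by 2.85 ± 0.16, the carbonic anhydrase Car12 by 2.81 ± 0.21 and Tmem26 by 2.64 ± 0.20. The matrix protein Spon2 rose by 2.38 ± 0.11, the receptor Gpr35 by 2.27 ± 0.23 and Pfkfb3 by 2.20 ± 0.13. Igfbp5, an IGF-binding protein, rose from 61.6 ± 7.49 to 287 ± 28.1 CPM (2.22 ± 0.31). Klhl24 (−2.83 ± 0.15), the actin-binding Shroom3 (−2.75 ± 0.21), cysteine dioxygenase (Cdo1, −2.71 ± 0.11) and Nipal3 (−2.50 ± 0.16) fell. In total 5797 genes were called, 2964 higher and 2833 lower, with 270 at least 2-fold higher and 449 at least 2-fold lower.

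Of the glycolysis and hypoxia response genes, 19 of the 21 tested members rose and 1 fell (19 and 1 adjusted over the list alone) at 6 h. The mitophagy receptor Bnip3 was at 1.46 ± 0.10 beside Egln3 and Pfkfb3, and the list had a camera adjusted p of 8.50e-19 and an adjusted p = 0.0156 with an estimated correlation. Of the ribosome biogenesis genes, 29 of the 31 tested members rose and 1 fell (29 and 1 adjusted over the list alone). Rrp12 was at 1.16 ± 0.099 and the pseudouridine synthase Dkc1 at 1.05 ± 0.086, and the list had a camera adjusted p of 3.92e-19 and an adjusted p = 0.00200 with an estimated correlation. Of the G1 and S phase genes, 21 of the 27 tested members rose and 0 fell (22 and 0 adjusted over the list alone). The replication licensing factor Cdc6 was at 2.11 ± 0.27, Uhrf1 at 1.53 ± 0.13 and the cyclins Ccne1 and Ccne2 at 1.43 ± 0.14 and 1.41 ± 0.17, and the list had a camera adjusted p of 3.08e-09 and an adjusted p = 0.00266 with an estimated correlation. Of the cyclin-dependent kinase inhibitors, 3 of the 7 tested members fell and 0 rose (4 and 0 adjusted over the list alone). Cdkn2b was at −0.69 ± 0.10, and the list had a camera adjusted p of 0.0292 and an adjusted p = 0.109 with an estimated correlation. Of the ER chaperones and secretory pathway genes, 16 of the 20 tested members rose and 0 fell (16 and 1 adjusted over the list alone). Hyou1 was at 0.90 ± 0.069 and Creld2 at 0.89 ± 0.087, and the list had a camera adjusted p of 2.83e-07 and an adjusted p = 0.127 with an estimated correlation. Of the cholesterol genes, 15 of the 24 tested members rose and 1 fell (17 and 1 adjusted over the list alone) (camera adjusted p = 1.82e-05, adjusted p = 0.199 with an estimated correlation), and of the fatty acid synthesis genes, 8 of the 11 tested members rose and 1 fell (8 and 1 adjusted over the list alone). The elongase Elovl6 was at 1.14 ± 0.076, and the list had a camera adjusted p of 0.00340 and an adjusted p = 0.346 with an estimated correlation. Of the inflammatory cytokines and NF-kB targets, 8 of the 17 tested members rose and 0 fell (8 and 0 adjusted over the list alone). The prostaglandin synthase Ptges was at 1.12 ± 0.087, and the list had a camera adjusted p of 0.0239 and an adjusted p = 0.353 with an estimated correlation.

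Of the FoxO targets, 13 of the 19 tested members fell and 2 rose (13 and 2 adjusted over the list alone) at 6 h. The pyruvate dehydrogenase kinase Pdk4 was at −1.94 ± 0.15, the ubiquitin ligase Fbxo32 at −1.78 ± 0.44 and Irs2 at −2.09 ± 0.14, and the list had a camera adjusted p of 2.04e-05 and an adjusted p = 0.0396 with an estimated correlation. Of the autophagy and lysosome genes, 12 of the 16 tested members fell and 0 rose (13 and 0 adjusted over the list alone). Gabarapl1 was at −1.19 ± 0.065 and Map1lc3b, both of which encode proteins of the autophagosome membrane, at −0.88 ± 0.067, and the list had a camera adjusted p of 1.25e-06 and an adjusted p = 0.0353 with an estimated correlation. Of the actin cytoskeleton and SRF or YAP targets, 7 of the 14 tested members fell and 0 rose (8 and 0 adjusted over the list alone). Ctgf was at −1.59 ± 0.20, and the list had a camera adjusted p of 0.00188 and an adjusted p = 0.139 with an estimated correlation. The tendon cell markers missed the threshold of camera at 6 h (adjusted p = 0.125) and passed it without 6 h replicate 2 (0.0362), and fry called them lower (0.00358). Of the Atf4 targets, 10 of the 26 tested members rose and 4 fell (10 and 4 adjusted over the list alone) at 6 h. That list missed the threshold of camera (adjusted p = 0.123) and passed it with the macrophage marker level as a term (0.0466).

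After 24 h of IGF1, mitotic genes were higher than at 0 h and actin cytoskeleton and SRF or YAP target genes lower. The mitotic kinase Plk1 rose from 2.75 ± 0.462 to 19.2 ± 2.95 CPM (2.80 ± 0.16, adjusted p = 1.94e-13), the mitotic kinesin Kif14 by 2.79 ± 0.23 and the spindle protein Aspm by 2.79 ± 0.21. Igfbp5 reached 888 ± 74.7 CPM (3.85 ± 0.33). Fam84a rose by 4.88 ± 0.38, from 0.244 ± 0.125 to 7.48 ± 1.33 CPM, and the skeletal muscle myosin Myh1 by 3.18 ± 0.31, to 5.43 ± 0.527 CPM. Dio3, which inactivates thyroid hormone, fell from 85.8 ± 4.27 to 14.8 ± 2.22 CPM (−2.53 ± 0.095). Heparin cofactor 2 (Serpind1, −2.51 ± 0.22), the aminopeptidase Lvrn (−2.45 ± 0.22), Fgd3 (−2.27 ± 0.16), Shroom3 (−2.26 ± 0.21), Ctgf (−2.25 ± 0.20) and Pim1 (−2.20 ± 0.13) fell as well. In total 3746 genes were called, 1836 higher and 1910 lower, with 385 at least 2-fold higher and 244 at least 2-fold lower.

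Of the G2 phase and mitosis genes, 26 of the 26 tested members rose and 0 fell (26 and 0 adjusted over the list alone) at 24 h. Ccnb2 was at 2.68 ± 0.16, Cenpf at 2.64 ± 0.19 and Bub1b at 2.59 ± 0.16, and the list had a camera adjusted p of 5.38e-42 and an adjusted p = 0.00138 with an estimated correlation. Of the G1 and S phase genes, 25 of the 27 tested members rose and 0 fell (25 and 0 adjusted over the list alone). Cdc6 was at 1.63 ± 0.28 and Mcm5, a subunit of the replicative helicase, at 1.40 ± 0.12, and the list had a camera adjusted p of 7.94e-16 and an adjusted p = 8.15e-04 with an estimated correlation. Of the cholesterol genes, 22 of the 24 tested members rose and 0 fell (23 and 0 adjusted over the list alone). Dhcr7 was at 0.92 ± 0.078 and Mvd at 0.87 ± 0.092, and the list had a camera adjusted p of 2.07e-18 and an adjusted p = 0.00668 with an estimated correlation. Of the fatty acid synthesis genes, 10 of the 11 tested members rose and 0 fell (10 and 0 adjusted over the list alone). Elovl6 was at 1.53 ± 0.076 and the desaturase Scd2 at 1.15 ± 0.064, and the list had a camera adjusted p of 1.14e-10 and an adjusted p = 0.0159 with an estimated correlation. Of the p53 target genes, 9 of the 14 tested members rose and 0 fell (10 and 0 adjusted over the list alone). Perp was at 1.41 ± 0.14 and Gdf15 at 0.96 ± 0.25, and the list had a camera adjusted p of 5.29e-05 and an adjusted p = 0.168 with an estimated correlation.

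Of the actin cytoskeleton and SRF or YAP targets, 13 of the 14 tested members fell and 0 rose (13 and 0 adjusted over the list alone) at 24 h. Ankrd1 was at −1.84 ± 0.11 and smooth muscle actin (Acta2) at −0.94 ± 0.16 beside Ctgf, and the list had a camera adjusted p of 1.83e-13 and an adjusted p = 0.00200 with an estimated correlation. Of the TGF-beta pathway genes, 10 of the 16 tested members fell and 2 rose (10 and 2 adjusted over the list alone). The activin subunit Inhba was at −1.27 ± 0.10 and the matrix protein Tgfbi at 1.17 ± 0.11, and the list had a camera adjusted p of 9.13e-04 and an adjusted p = 0.0353 with an estimated correlation. Of the ER chaperones, 9 of the 20 tested members fell and 0 rose (11 and 0 adjusted over the list alone). Hspa5 was at −0.46 ± 0.058, and the list had a camera adjusted p of 0.00193 and an adjusted p = 0.402 with an estimated correlation. Of the inflammatory cytokines and NF-kB targets, 7 of the 17 tested members fell and 2 rose (8 and 2 adjusted over the list alone). Ccl20 was at −2.55 ± 0.52, and the list had a camera adjusted p of 0.0216 and an adjusted p = 0.353 with an estimated correlation. Of the ribosomal proteins, 7 of the 20 tested members fell and 0 rose (9 and 0 adjusted over the list alone). Rpl4 was at −0.34 ± 0.077, and the list had a camera adjusted p of 0.0150 and an adjusted p = 0.803 with an estimated correlation, and was not called by fry (adjusted p = 0.213). Of the autophagy and lysosome genes, 6 of the 16 tested members fell and 1 rose (6 and 1 adjusted over the list alone). The protease Ctsl was at −0.49 ± 0.060, and the list had a camera adjusted p of 0.0292 and an adjusted p = 0.399 with an estimated correlation. Without 24 h replicate 1 the calls of these last lists were lost, with adjusted p at 0.0517 for the inflammatory list, 0.0549 for the ribosomal proteins and 0.0721 for autophagy. Of the immediate early genes, 7 of the 22 tested members fell and 3 rose (7 and 4 adjusted over the list alone). Maff was at −1.65 ± 0.094, Dusp1 at −1.59 ± 0.11 and Egr1, which rose, at 1.13 ± 0.19, and the list had a camera adjusted p of 0.0432 and an adjusted p = 0.647 with an estimated correlation. That call was lost without 0 h replicate 1 (0.0630), 0 h replicate 4 (0.0554), 2 h replicate 4 (0.0630), 24 h replicate 1 (0.0733) or 24 h replicate 4 (0.0577), without 2 h replicates 2 and 4 (0.0701), and with the macrophage marker level as a term (0.0584).

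**Figure D4:**
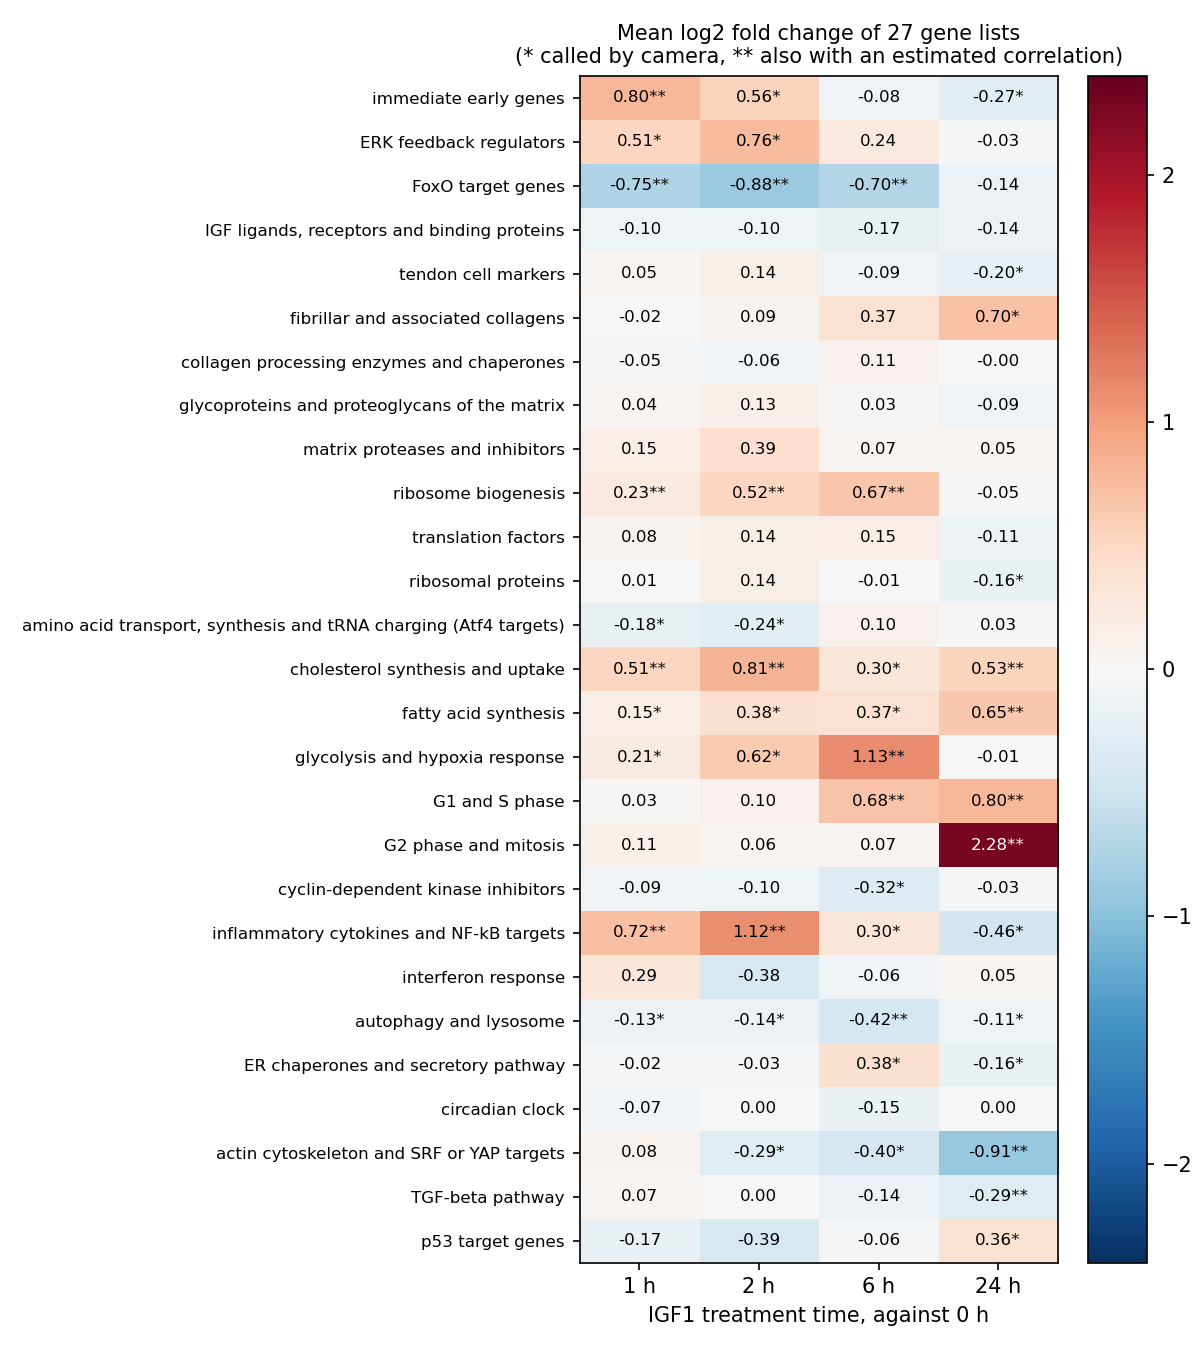
Mean log2 fold change against 0 h (colour and printed value) of the 27 gene lists that are not markers of other cell types (rows) at each IGF1 time (columns), with 1 star where camera called the list and a pair of stars where the call held with an estimated correlation. The highest mean was 2.28 for G2 phase and mitosis at 24 h and the lowest −0.91 for the actin cytoskeleton list at 24 h.

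With all libraries, the tendon transcription factor scleraxis (Scx) rose at 1, 2 and 6 h and was not called at 24 h. Scx was at 1736 ± 81.2 CPM at 0 h, 4136 ± 467 at 1 h (1.25 ± 0.11, adjusted p = 3.42e-08), 4354 ± 968 at 2 h (1.33 ± 0.11), 2194 ± 103 at 6 h (0.34 ± 0.11, adjusted p = 0.0158) and 1577 ± 105 at 24 h (−0.14 ± 0.11, adjusted p = 0.387). In a fit of only the 8 libraries compared, Scx was called at 24 h (−0.13, adjusted p = 0.0144). Mohawk (Mkx), another tendon transcription factor, fell at 2 h (−0.90 ± 0.075) and 6 h (−0.51 ± 0.074). Its smaller changes at 1 h (−0.25 ± 0.074, adjusted p = 0.0272) and 24 h (−0.20 ± 0.074, adjusted p = 0.0470) lost their calls when single libraries were left out. At 1 h these were 0 h replicates 3 (adjusted p = 0.0924) and 4 (0.0830) and 1 h replicates 1 (0.0540), 2 (0.0780) and 3 (0.0793). At 24 h the adjusted p was 0.0533, 0.131 and 0.118 without 0 h replicates 1, 3 and 4, 0.0555, 0.0550, 0.0552 and 0.0505 without 1 h replicates 1 to 4, 0.0563, 0.0587 and 0.0578 without 6 h replicates 1, 3 and 4, and 0.139, 0.102 and 0.0992 without 24 h replicates 2, 3 and 4. Tenomodulin (Tnmd) was not called at any time (adjusted p from 0.609 at 6 h to 0.988 at 2 h, with log2 −0.05, 0.00, 0.12 and −0.02 at 1, 2, 6 and 24 h). Of the tendon cell markers, 8 of the 14 tested members fell and 2 rose (8 and 3 adjusted over the list alone) at 24 h. The membrane lectin Chodl was at −1.54 ± 0.077, keratocan (Kera) at 1.29 ± 0.34 and Thbs4 at −0.71 ± 0.059, and the list had a camera adjusted p of 0.00184 and an adjusted p = 0.353 with an estimated correlation. The median (−0.25) and mean (−0.20) of that list had the sign of its test.

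Of the fibrillar and associated collagens, 8 of the 13 tested members rose and 1 fell (8 and 1 adjusted over the list alone) at 24 h. Col15a1 was at 2.36 ± 0.72, Col5a3 at 1.75 ± 0.25, Col6a3 at 1.72 ± 0.15 and Col14a1 at 1.48 ± 0.14, and the list had a camera adjusted p of 2.78e-04 and an adjusted p = 0.323 with an estimated correlation. The call of Col15a1 was lost without 0 h replicate 2 (adjusted p = 0.0609), 0 h replicate 3 (0.0522), 0 h replicate 4 (0.0621) or 24 h replicate 4 (0.0564). Col3a1 rose from 2283 ± 35.9 to 5337 ± 79.8 CPM at 24 h (1.22 ± 0.083) and by 0.31 ± 0.082 at 6 h, and was at −0.05 ± 0.082 at 1 h and −0.00 ± 0.082 at 2 h (adjusted p = 0.785 and 0.984). Without 2 h replicate 2 the 2 h value of Col3a1 was −0.15 (adjusted p = 0.0375), and without 2 h replicates 1 and 2 it was −0.19 (adjusted p = 0.0156). Col1a1 and Col1a2, which encode the chains of type I collagen, fell at 2 h. Col1a1 was at −0.17 ± 0.11, −0.44 ± 0.11, −0.20 ± 0.11 and 0.09 ± 0.11 at 1, 2, 6 and 24 h (adjusted p = 0.411, 0.00357, 0.169 and 0.599). Col1a2 was at −0.14 ± 0.089, −0.43 ± 0.089, −0.30 ± 0.089 and −0.05 ± 0.089 (adjusted p = 0.387, 4.23e-04, 0.00804 and 0.718). The 2 h falls of Col1a1 and Col1a2 lost their calls with the macrophage marker level as a term (−0.19, adjusted p = 0.271, and −0.20, adjusted p = 0.101), which also takes up part of any 2 h difference. That of Col1a1 was also lost without 2 h replicates 1 and 2 (−0.31, adjusted p = 0.0684) or 2 and 4 (−0.24, adjusted p = 0.126). At 6 h Col1a1 was called without a count filter (0.0218) and in a fit of only the 8 libraries compared (0.0207).

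Of the IGF axis, Igf1r, Insr and Igf1 were called lower at 2 h and 24 h. The IGF1 receptor (Igf1r) was at 192 ± 19.9, 178 ± 16.1, 145 ± 19.7, 109 ± 5.68 and 78.7 ± 1.48 CPM at the 5 times (−0.11 ± 0.083, −0.40 ± 0.083, −0.82 ± 0.084 and −1.28 ± 0.085 against 0 h, adjusted p = 0.490, 4.35e-04, 1.04e-08 and 5.31e-12). The insulin receptor (Insr) fell at 2 h (−0.81 ± 0.092), 6 h (−0.60 ± 0.091) and 24 h (−0.34 ± 0.091), and at 1 h (−0.22 ± 0.090, adjusted p = 0.124) was called without 2 h replicate 4 (0.0062), without 2 h replicates 1 and 2 (0.0241) or 2 and 4 (0.00416), with 1 surrogate variable (0.00963) and in a fit of only the 8 libraries compared (0.00729). Igf1 itself was at −0.02 ± 0.059, −0.21 ± 0.059, −0.06 ± 0.059 and −0.52 ± 0.059 at 1, 2, 6 and 24 h (adjusted p = 0.916, 0.00569, 0.441 and 9.57e-08). The 2 h call of Igf1 was lost in a fit of only the 8 libraries compared (0.0621). Irs2 was at −1.60 ± 0.14 at 24 h. The metalloprotease Pappa, which cleaves IGF-binding proteins, was at −1.44 ± 0.25 at 6 h. As a list, the IGF ligands, receptors and binding proteins were not called by camera at any time, with the lowest adjusted p of 0.103 at 24 h, when 9 of the 18 tested members fell and 4 rose (11 and 5 adjusted over the list alone). Fry called this list lower at 2, 6 and 24 h (adjusted p = 0.00202, 0.00711 and 0.00190). Its mean log2 CPM was 5.95, 6.10, 5.90 and 5.55 in 2 h replicates 1 to 4, and 5.97 to 6.10 at 0 h. The 2 h fall therefore leans on 2 h replicate 4, where longer transcripts were lower, and fry was not run without that library.

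The remaining lists were called by camera with all libraries at no time against 0 h. The collagen processing enzymes and chaperones had a lowest camera adjusted p of 0.294 at 1 h. At 6 h, 5 of the 19 tested members rose and 2 fell (5 and 2 adjusted over the list alone), with the lysyl hydroxylase Plod2 at 1.11 ± 0.080. Of all tested genes, 40.2% were called at that time. Fry called the list higher at 6 h (0.0119), where its mean log2 fold change was 0.107 and its median −0.0195. The glycoproteins and proteoglycans of the matrix had a lowest camera adjusted p of 0.428 at 24 h, when 6 of the 19 tested members fell and 5 rose (7 and 6 adjusted over the list alone), with thrombospondin 1 (Thbs1) at −1.72 ± 0.10, versican (Vcan) at 1.20 ± 0.13 and periostin (Postn) at 1.16 ± 0.29, and fry called the list lower (0.00156). The matrix proteases and inhibitors had 0.719 at 2 h, when 6 of the 20 tested members rose and 3 fell (6 and 3 adjusted over the list alone), with Adamts15 at 1.72 ± 0.22 and Adamts5 at −1.11 ± 0.092. The translation factors had 0.0832 at 24 h, when 6 of the 17 tested members fell and 0 rose (6 and 0 adjusted over the list alone), and passed the threshold there without 0 h replicate 1 (0.0464), 2 h replicate 4 (0.0491) or 2 h replicates 2 and 4 (0.0437), and at 2 h without 2 h replicates 1 and 2 (0.0472). By fry it was called higher at 1, 2 and 6 h and lower at 24 h (adjusted p = 0.0382, 5.83e-04, 2.79e-04 and 0.00251). The mean log2 CPM of the translation factors was 8.81 in 2 h replicate 4, where longer transcripts were lower. It was 8.65 to 8.67 in the other 2 h libraries and 8.53 to 8.58 at 0 h. Fry was not run without 2 h replicate 4. The interferon response list had 0.205 at 2 h, when 1 of the 15 tested members fell and 0 rose (0 and 0 adjusted over the list alone). The circadian clock list had 0.377 at 1 h, when 4 of the 17 tested members fell and 1 rose (4 and 3 adjusted over the list alone), with the repressors Bhlhe40 and Nr1d1 at 1.55 ± 0.087 and −1.28 ± 0.098, and at 6 h 7 of the 17 tested members fell and 6 rose (7 and 6 adjusted over the list alone), with Per3 at −1.70 ± 0.12 and Dbp at −1.38 ± 0.22, when fry called the list lower (0.00309). Lists at the other times, not given here one by one, are in the plot of mean log2 fold changes.

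With all libraries, camera called 2 of the lists of markers of other cell types, the macrophage markers at 2 h and the skeletal muscle markers at 24 h. Fry called these and also the skeletal muscle (0.0278) and adipocyte (0.0201) markers higher at 2 h. It called the keratinocyte markers lower at 2 h (0.00114) and 6 h (8.68e-04), the endothelial markers lower at 6 h (2.37e-04), and the chondrocyte markers lower at 6 h (0.00987) and 24 h (0.00146). The 5 marker lists that fry called at these further times have 2 to 5 tested members each. Of the skeletal muscle markers, 2 of the 4 tested members rose and 0 fell (2 and 0 adjusted over the list alone) at 24 h. Myh1 and Myh4 were in front, and the list had a camera adjusted p of 0.0256 and an adjusted p = 0.216 with an estimated correlation. Myh4 was at 1.48 ± 0.265 CPM at 24 h and had no count in 0 h replicates 1, 3 and 4, so no fold change is given, and near-identical myosin genes can share reads. This list call was lost without 24 h replicate 2 (0.128) and without 2 h replicates 2 and 4 (0.0541). The macrophage markers passed the threshold at 1 h only without 1 h replicate 2 (0.0301, against 0.272 with all libraries). The lowest camera adjusted p of the other marker lists was 0.332 for endothelial markers at 6 h, 0.555 for pericyte and smooth muscle markers at 2 h, 0.526 for Schwann cell markers at 6 h, 0.133 for chondrocyte markers at 24 h, 0.377 for adipocyte markers at 2 h and 0.355 for keratinocyte markers at 6 h. At 2 h, 2 of the 6 tested members rose and 0 fell (2 and 0 adjusted over the list alone) of the Schwann cell list, Sox10 (3.66 ± 1.35) and Cdh19 (3.62 ± 1.03), and without 2 h replicate 2 they were at 1.34 and 1.28 and both calls were lost (adjusted p = 0.441 and 0.128). The call of Sox10 was also lost without 0 h replicates 1 (0.0952), 3 (0.0969) or 4 (0.0894), 1 h replicate 1 (0.0514), 6 h replicate 3 (0.0508), 24 h replicate 2 (0.0504) or 24 h replicate 3 (0.0509), and with 1 surrogate variable (0.0522), with log2 values of 3.29 to 3.66. In a fit of only the 8 libraries compared, Sox10 was at 3.67 (0.119) and Cdh19 at 3.64 (0.105), neither called. Without 2 h replicates 2 and 4 they were at 1.58 (0.444) and 1.57 (0.0707), and without 2 h replicates 1 and 2 at 0.21 (0.939) and 0.45 (0.687).

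The steps between successive times tested whether the effects at neighbouring times differed. From 1 h to 2 h, 2357 genes changed, 1082 higher and 1275 lower, with the kinase Itpk1 at 1.82 ± 0.12 and Crebrf and Klhl24 at −1.77 ± 0.093 and −1.64 ± 0.14. That count was 773 in a fit of only the 8 libraries of these times and 1218 with the macrophage marker level as a term. From 2 h to 6 h, 3944 genes changed, 1964 higher and 1980 lower, with Car12 at 2.19 ± 0.21 and Runx1t1 at 1.89 ± 0.11, and with Egr3, Cdo1 and Nr4a3 at −2.82 ± 0.24, −2.48 ± 0.11 and −2.39 ± 0.24. The count was 2549 in a fit of only the 8 libraries. From 6 h to 24 h, 5166 genes changed, 2537 higher and 2629 lower. Ccnb2 (3.06 ± 0.16), Fam84a (3.04 ± 0.32) and Cenpf (2.81 ± 0.19) rose over that step, and the 6 h risers Egln3 (−2.47 ± 0.16), Apln (−2.36 ± 0.20) and Gpr35 (−2.34 ± 0.24) fell.

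The authors' deposited table of edgeR results holds 12207 genes and calls 1518, 5324, 5636 and 3713 genes at 1, 2, 6 and 24 h against 0 h at an adjusted p under 0.05. Of these, 1428, 5181, 5502 and 3588 were also called here, all with the same sign. For the steps, the authors' deposited table calls 2434, 3932 and 5096 genes, of which 2251, 3810 and 4941 were called here.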

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

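The test of a trend with GC content was set out before its result was seen; the other tests given here, splits of the libraries included, were written down only after the values they rest on had been seen. A summed muscle test was changed on the way, and tests of macrophage marker ratios and of other myosin genes were left out, as said with each.

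The macrophage markers rose together at 2 h but unevenly across the libraries. Their deviations from the group means had a median pairwise correlation of 0.841 over the 20 libraries, against at most 0.201 in 200 random lists. A share of macrophages that varies between libraries would give this, and so would regulation of the markers together, which random lists cannot tell apart. The correlation that camera estimated was 0.817 for the macrophage markers, 0.839 for the ribosomal proteins and 0.789 for the interferon response. Markers of other cell types moved in the same library: of all 20 libraries, 2 h replicate 2 also had the highest mean log2 CPM of Schwann cell (2.84, others at most 1.56), endothelial (2.32, others at most 1.48), pericyte and smooth muscle (2.78, others at most 1.74) and adipocyte markers (1.88, others at most 1.71). It was the lowest 2 h library for chondrocyte (2.04) and keratinocyte markers (0.173). A difference of that library in several cell types therefore stays open and was not tested. A rise in every 2 h culture in response to IGF1 stays open: the lowest 2 h library differed by −0.414 from the highest library of the other times and by 0.484 from the highest 0 h library. The markers rose by log2 0.83 to 2.21, and a test of whether they kept 1 fixed ratio was left out after its result was seen because it rested on 1 library. All 13 have at least 1 CPM at 0 h, none is in another list, and the most abundant is Lyz2 at 215 CPM, so activation of macrophages already present may also contribute and was not tested.

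Across genes, 2 h replicate 4 stood apart from the other 2 h libraries, with an SD of its deviations of 0.284 against 0.0874 to 0.205 in the other libraries. For this library, library size is argued against by 6 libraries with a lower total count, and a trend with GC content by a partial correlation of −0.181 given length. In the other libraries the size of that partial correlation ranged from 0.00981 in 1 h replicate 2 to 0.626 in 0 h replicate 1. It was −0.490 in 1 h replicate 4, and the effect of such trends on the comparisons was not tested. The deviation of 2 h replicate 4 followed transcript length with a Spearman correlation of −0.739 across 9436 genes, against a size of at most 0.289 at the other times. Removing that trend left an SD of 0.200, so RNA integrity or library preparation in that library may differ, which the labels do not record. No biological explanation was tested.

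Myh1 was higher in all 4 libraries at 24 h than in any at 0 h, with a ratio of medians of 9.49. Skeletal muscle shared by the 24 h cultures was tested with the median sum of 8 abundant muscle transcripts. At 24 h that median was 1.06 times that at 0 h, a test that cannot register muscle in a single library. The sum was only 3.22 to 3.94 CPM at 0 h. At that level a fall of 1 transcript can offset a rise of the others, so shared muscle stays open. The first form of that test counted 24 h libraries with a sum above every 0 h library and gave 2 of 4, with 24 h replicate 2 at 17.7 CPM, 24 h replicate 3 at 4.06 CPM and a range of 3.22 to 3.94 CPM at 0 h; it was replaced after that result was seen. In 24 h replicate 2, Myh3 was at 4.28, Myh8 at 2.29 and Acta1 at 6.45 CPM, against at most 0.164, 0.109 and 2.69 CPM at 0 h. The other 24 h libraries had at most 0.629, 0.129 and 1.77 CPM of these genes, so muscle in 24 h replicate 2 stays open. Reads shared with another myosin heavy chain gene stay open. Myh4 was at 1.16 to 1.77 CPM at 24 h and 0 to 0.0508 CPM at 0 h, and a test on other myosin genes was left out after its result was seen because only the distant Myh9, Myh10 and Myh11 passed its CPM limit. A response to IGF1 and time in culture stay open as untested.

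Other splits of the libraries were refitted, and the real times gave the most called genes in each comparison. Every other split mixes libraries of different times, so a real difference between times widens the spread and lowers the count. The low counts of the other splits are therefore no measure of chance calls. For 2 times, 1 of 35 is also the smallest share that such a test can reach. Only the real split, 1 of 35, gave as many genes at 1 h (1533, highest other 0), 2 h (5443, highest other 246), 6 h (5797, highest other 0) and 24 h (3746, highest other 1). The same held for the steps from 1 h to 2 h (1 of 35, 2357, highest other 624), from 2 h to 6 h (1 of 35, 3944, highest other 482) and from 6 h to 24 h (1 of 35, 5166, highest other 0). For any change over the 5 times it was 1 of 100 (9188, highest other 504). The splits with 246, 624 and 482 genes all regroup 2 h libraries.

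In 15 of 350 groups of 4 libraries, 1 library lay apart from the rest by Dixon's ratio of gap to range above the critical value for 4 samples, where chance gives about 1 in 20. The ratio was 0.967 for Hes1 and 0.841 for Spry4 in 0 h replicate 2. It was 0.937 for Chac1, 0.865 for Acta2 and 0.884 for Ctsl in 0 h replicate 1, and 0.852 for Dbp and 0.8291 for Ccnb2 in 0 h replicate 4. In 2 h replicate 4 it was 0.847 for Runx1t1, 0.921 for Fasn, 0.866 for Ccl2 and 0.908 for Ccl7, and in 2 h replicate 2 0.893 for Sema7a. It was 0.861 for Igfbp5 in 6 h replicate 2, 0.836 for Insr in 6 h replicate 3, and 0.840 for the mitochondrial share of counts in 1 h replicate 4 (1.68% against 1.36% to 1.41%).

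A total of 12 named genes were called in opposite directions at different times against 0 h, with a called difference between those times in the same edgeR fit. Going from 1 h to 6 h the log2 value changed by −3.61 for Egr3 and −3.03 for Nr4a3. Going from 1 h to 24 h it changed by −2.07 for Lif and −2.23 for Maff. Going from 2 h to 24 h it changed by −2.74 for Ccl2, −3.60 for Ccl20, −3.15 for Dio3 and 1.32 for Trib3. Going from 6 h to 24 h it changed by −1.98 for Bnip3, −1.09 for Hyou1, −1.09 for Hspa5 and 2.33 for Dbp.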

How the results depend on the processing

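Leaving out 2 h replicates 1 and 2, leaving out 2 h replicates 2 and 4, the macrophage marker level as a term, and leaving out single libraries in the list tests were chosen after seeing the data. The count of called genes at 2 h was 3238 with the marker level as a term and that of the step from 1 h to 2 h was 1218. Every 2 h library had a higher marker level than any 0 h library, so this term also takes up part of any other 2 h difference. Fits of only the 8 libraries compared gave fewer genes in the comparisons that hold the 2 h libraries, 3654 at 2 h, 773 for that step and 2549 for the step from 2 h to 6 h. They gave more in the others, 2068 at 1 h, 6995 at 6 h, 4931 at 24 h and 6680 for the step from 6 h to 24 h. At 1 h, 2429 genes were called without 2 h replicates 2 and 4. With an estimated correlation 20 of the 48 list calls held, and fry, which tests a list without other genes, gave 71. In the fit of all libraries the groups share 1 estimate of the spread. Deviations from a time's mean had an SD of 0.1304 to 0.284 in the 2 h libraries and at most 0.1301 in the others. The shared estimate is therefore likely too small for 2 h and too large for the other times. The counts in the fits of 8 libraries moved in that direction. How much of their change this explains, and the cause of the other differences, were not tested. The other planned and added counts stayed within 1.5 times of the reported ones. The lowest share of the called genes kept under an alternative was 32.7%, for the step from 1 h to 2 h in the fit of 8 libraries, and 56.3% at 2 h with the marker level as a term.

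With the marker level as a term, Sox10 at 2 h turned to −1.98, Ngfr to −0.57 and Cdh19 to −0.11, none called, and the cause was not tested. Leaving out 1 library at a time gave 1191 to 2162 genes at 1 h, 4805 to 5693 at 2 h, 5133 to 6631 at 6 h and 3130 to 4659 at 24 h, each highest without 2 h replicate 4. It gave 1616 to 2739 for the step from 1 h to 2 h, 3168 to 4570 from 2 h to 6 h, 4427 to 6036 from 6 h to 24 h, 8675 to 10064 for any change, and 43 to 49 list calls. The replicate number as a block gave 1518, 5361, 5752 and 3677 genes at 1, 2, 6 and 24 h, 2250, 3857 and 5111 for the steps, 9096 for any change and 48 list calls. Libraries share only a number: 1 of 40 pairs of the same number had a correlation of deviations over 0.1 (median −0.00388), and 3 of 20 libraries correlated best with their own number. RLE scaling moved the median fold change by at most 0.0117 in size (−0.0117 at 1 h). At this depth 68% of simulated 1.5-fold changes at 1 h were recovered, so smaller changes can be missed.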
